A study of Sus scrofa with 3 samples.

How the data were processed

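Small RNA libraries of pig liver were made at 3 stages, E90, P30d and P7y, from male Jinhua pigs, with 1 library per stage. Per the labels, total RNA with an integrity number above 6.0 was isolated with a kit for small RNA, about 15 µg of it enriched for small RNA, and fragments of 14 to 40 nt were ligated to adaptors, amplified by PCR and sequenced on a Genome Analyzer II. The libraries were grouped by the stage that their labels give, and replicate spread could not be measured.

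The authors deposited 1 table per library with a line for each arm of each hairpin. Per the file headers, the authors mapped reads to miRNA hairpins of pig and other mammals from miRBase, placed hairpins and reads on the pig genome and on expressed sequence tags, and sorted each hairpin into groups, the last of which holds predicted hairpins without a known miRNA. The deposited read numbers per arm are expected counts, since a read that maps to several hairpins is divided among them, and the deposited values of the reads without and with a mismatch are estimated counts of the same kind. The deposited number of reads per hairpin and the deposited number of copies of the representative read of an arm are counts. The submitters' processing notes name Sscrofa10.2 as the genome build, and coordinates are those of the tables. The miRBase release, the aligner, the adapter trimming and the number of mismatches allowed are not given in the sources used here. No genome or gene annotation was used, so whether hairpins lie in exons or introns was not analysed here.

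Expected counts were summed over the copies of each mature miRNA, without species prefix, copy number or end variant, and rounded to whole numbers. Of 1006 names, 26 were merged into others because the same representative read, of 18 nt or more, held over 50% of the reads of each. This rule was chosen after the tables were seen, since the same miRNA bears different names in different tables. A further 14 rounded to 0 reads in every library, which left 966 mature miRNAs with a read. CPM were computed per 1000000 reads of named miRNAs, so predicted hairpins were left out of the total. The comparisons kept the 320 miRNAs with a mean of 10 CPM or more over the 3 libraries. For each pair of libraries the log2 ratio of CPM, later over earlier, was given with an exact conditional binomial 95% interval. A miRNA was called higher or lower where the absolute log2 ratio was 1 or more and the interval excluded 0. A count of 0 was set to 3 reads for the size of a ratio. A relative log2 ratio is the log2 ratio minus the median of all 320. Shares of reads have exact Clopper-Pearson intervals. The balance of arms was the log2 of 5p over 3p reads with 0.5 added to each, with an exact conditional interval of the odds ratio, for hairpins with at least 50 reads in each library. No p-values are given, since 1 library per stage has no residual spread.

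The lists of miRNAs were hepatocyte, let-7, miR-30, miR-99 with miR-100 and miR-125, miR-17-92, erythroid, leukocyte, endothelial, mesenchymal, biliary, DLK1-DIO3, IGF2-H19 (measured through miR-483-3p alone), ageing, muscle, neural, pancreas and pluripotency (embryonic stem cells). Some lists share members, such as miR-424 in leukocyte and endothelial, miR-10b in endothelial and mesenchymal, miR-21 in mesenchymal and ageing, miR-146a in leukocyte and ageing and miR-375 in biliary and pancreas. For each list the members higher and lower were counted, and the median log2 ratio was placed among 10000 random lists of the same size drawn from 10 bins of mean expression, as a description of these libraries. Named miRNAs were the 10 most abundant of each library, the 10 with the largest ratio in each direction of each pair among those with a mean of 100 CPM or more and an interval off 0, up to 4 members of each list with the highest mean, and miR-122 and let-7. Groups, lists, the tests of the comparisons, the naming rule and the first set of alternatives were chosen before the data were examined.

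The alternatives were TMM factors (edgeR 4.0.16), median-of-ratios size factors (DESeq2 1.42.0), a total without the 5 most abundant miRNAs of any library, no filter, a filter at 100 CPM, known pig miRNAs only, reads without a mismatch only, reads split among names, the representative read only, the more abundant arm of each list member only, and at least 200 reads per hairpin for arms. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and R 4.3.3, and plots matplotlib 3.10.9. The comparison was tested on simulated data with Poisson counts at the real totals, with 200 of 320 miRNAs changed by known folds. At 3-fold it recovered 99.0% from E90 to P30d and 100.0% in the other pairs, it recovered 100.0% at 8-fold, called 0% of unchanged miRNAs, and its intervals held the true value for 95.6%, 94.4% and 95.0% of miRNAs from E90 to P30d, P30d to P7y and E90 to P7y. Simulated counts hold no spread between animals, so these shares describe counting error alone. The simulated changes went up and down in equal numbers and the totals were taken as known. A shift in composition between libraries could therefore not arise, and the 0% does not cover calls that depend on scaling.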

Results

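Small RNA was sequenced from the liver of male Jinhua pigs, a Chinese breed, at embryonic day 90 (E90, late gestation), postnatal day 30 (P30d) and postnatal year 7 (P7y). The labels name 3 pigs per stage and give 1 library per stage, and they do not say whether RNA was pooled. There were therefore no replicates, and no difference described here has a replicate check. The 3 tables held 9406525 reads at E90, 3775157 at P30d and 9935073 at P7y, of which 98.3%, 96.0% and 99.9% lay in hairpins named as known miRNAs of pig or other mammals. A count of 0 allowed up to 0.325 counts per 1000000 miRNA reads (CPM) at E90, 0.828 at P30d and 0.302 at P7y. Intervals are 95% and, like these limits, cover counting error only, because there is 1 library per stage. Reads amplified by PCR are not independent molecules, so even counting error may be understated. Every comparison of reads sets libraries against each other, not conditions.

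The first question was which miRNAs made up the liver profile at each stage. The hepatocyte miRNA miR-122-5p, the best-known liver-specific miRNA, was the most abundant at E90 with 12.8% of miRNA reads and at P30d with 21.4%, while at P7y it held 3.79% and miR-192-5p, a miRNA of liver and gut, was the most abundant with 15.5%. The hairpin of miR-122 lies on chromosome 1 from 179916327 to 179916422 on the minus strand, and that of miR-192 on chromosome 2 from 6416971 to 6417077 on the plus strand (Sscrofa10.2 coordinates). Beside them, miR-99a-5p, miR-148a-3p, miR-30a-5p and miR-100-5p were among the 10 most abundant miRNAs of all 3 libraries. The other places differed between libraries. miR-101-3p held 65392 CPM at E90, 5493 at P30d and 119966 at P7y, and miR-143-3p, a miRNA of smooth muscle and fibroblasts, held 51123 CPM, 17730.4 and 102623. In the opposite sense, miR-26a-5p stood at 19843 CPM, 102238 and 25361, and miR-199a-5p, a miRNA of mesenchymal cells, at 3349 CPM, 40212 and 2539. miR-152-3p was among the 10 most abundant at E90 alone, with 26956 CPM against 2063 at P30d and 4751 at P7y. The other arm of the miR-101 hairpin, miR-101-5p, did not follow miR-101-3p, with 8 reads at E90, 97 at P30d and 9 at P7y.

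Together the 10 most abundant miRNAs held 63.99% of miRNA reads at E90 (exact Clopper-Pearson interval 63.96 to 64.02), 65.84% at P30d (65.79 to 65.88) and 74.90% at P7y (74.87 to 74.93). The hepatocyte miRNAs fixed in advance as a list held 41.7%, 39.3% and 42.8% in the order E90, P30d and P7y. Of 966 mature miRNAs with at least 1 read, 475 were read in all 3 libraries, and the libraries held 782, 734 and 563. At 10 CPM or more there were 321 at E90, 317 at P30d and 246 at P7y. The comparisons used the 320 miRNAs with a mean of 10 CPM or more, of which 315 were read in every library.

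**Figure D1:**
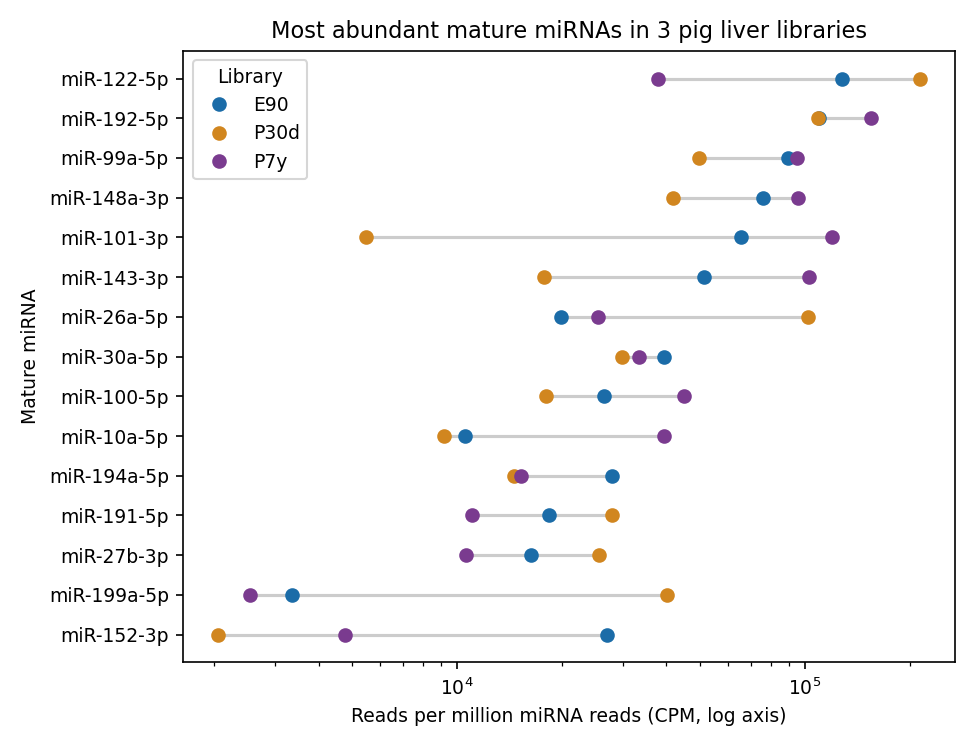
CPM (log axis) of the 15 mature miRNAs that ranked among the 10 most abundant of at least 1 library, with 1 point per library and a grey line over their range. miR-101-3p and miR-143-3p were lowest at P30d, miR-199a-5p and miR-26a-5p were highest there, and miR-122-5p was lowest at P7y, at 37869.7 CPM.

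The comparison of E90 with P30d spans birth and the first weeks of growth. miRNAs of the imprinted DLK1-DIO3 locus, which are transcribed from the maternal chromosome and are typical of fetal tissue, were lower at P30d in 19 of 20 measured cases, while 10 of 14 measured members of the let-7 family, which accumulates as tissues differentiate, were higher. The DLK1-DIO3 list had 70 members with a read, of which 20 passed the filter. A filter on the mean of the libraries can pass members high at E90 alone, so counts of members lower later may be partly set by it. Among DLK1-DIO3 miRNAs, miR-127-3p went from 2728 to 385 CPM (log2 ratio -2.82, interval -2.90 to -2.75), miR-409-5p from 2039 to 83.9 and miR-381-3p from 350 to 168. The exception, miR-380-3p, named after its value was seen, stood at -0.98. Among let-7 miRNAs, let-7a-5p went from 3530 to 16430.4 CPM (2.22, 2.20 to 2.24) and let-7b-5p from 319 to 2260.0, whereas let-7g-5p and let-7f-5p differed by 0.30 and 0.42, less than the 2-fold size rule. miR-483-3p, which is hosted by the imprinted growth factor gene IGF2, was lower at P30d as well, at 27.1 CPM against 456. The liver-enriched miR-802-5p, a regulator of glucose metabolism, went from 2.27 to 685 CPM (8.24, 7.62 to 8.93), the largest log2 ratio among miRNAs with a mean of at least 100 CPM.

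Compared with 10000 random lists of the same size matched on expression, the DLK1-DIO3 median of -3.24 stood at percentile 0 and the let-7 median of 1.80 at percentile 99.6, or 93.3 with only the more abundant arm of each member. The miR-17-92 cluster and its paralogs, miRNAs linked to cell proliferation, had 9 of 14 members lower and 0 higher at P30d (median -1.31, percentile 3.14), among them miR-20a-5p at -4.55, miR-25-3p at -1.48 and miR-19b-3p at -1.27. Of 9 erythroid miRNAs 6 were lower and 2 higher (median -1.56, percentile 3.25): miR-451-5p, which is abundant in red cells, was at -1.56 and miR-486-5p at -1.36, while miR-16-5p was at 1.98. Summed over the list, erythroid reads did not follow the median, with 1.07% of miRNA reads at E90, 1.24% at P30d and 0.287% at P7y. The arms of miR-144 parted, with miR-144-5p at -4.42 and miR-144-3p at 0.29. Of 14 leukocyte miRNAs 6 were higher, including miR-146a-5p at 4.34, miR-142-5p at 2.98 and miR-181a-5p at 1.57, and 3 were lower, including miR-424-5p at -1.66.

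Hepatocyte miRNAs went both ways, with 11 of 23 higher and 3 lower (median 0.97, percentile 96.5, and 0.37 at percentile 82.95 with only the more abundant arm of each member). miR-122-5p was at 0.74 and its other arm, miR-122-3p, at 4.21, miR-192-3p was at 3.52, and miR-101-3p was at -3.57, while miR-192-5p was at 0.00 under CPM with a sign that turned between scalings. Mesenchymal miRNAs had 7 of 18 higher and 3 lower, with miR-199a-5p at 3.59 against miR-152-3p at -3.71 and miR-143-3p at -1.53. The miR-30 family had 5 of 9 higher and 1 lower, with miR-30c-5p at 1.66, miR-30a-5p at -0.39, miR-30d-5p at -0.51 and miR-30e-5p at 0.01 under CPM with a sign that turned between scalings. Its median of 1.54 became 0.01 with only the more abundant arm of each member, and its share of reads was 7.76% at E90, 6.98% at P30d and 5.46% at P7y. The list of miRNAs linked to ageing had 6 of 11 higher and 1 lower, with miR-22-3p at 2.75. Biliary and epithelial miRNAs had 4 of 7 lower and 2 higher, with miR-375-3p at -3.63, miR-200b-3p at -2.42 and miR-200a-3p at 1.12. Endothelial miRNAs had 2 of 10 higher and 3 lower, with miR-126-3p, the most abundant member, at -0.67, its other arm miR-126-5p at 1.61 and miR-221-3p at -1.26. The miR-99, miR-100 and miR-125 families had 2 of 7 higher and 2 lower, with miR-125b-5p at 2.43 and miR-99b-5p at -1.37.

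Markers of other tissues were rare in the 3 libraries. The striated muscle list held 0.0176% of miRNA reads at E90, 0.0383% at P30d and 0.00847% at P7y, and the neural list 0.0194%, 0.0224% and 0.00638%. The pancreas list, of which miR-375-3p alone passed the filter, held 0.134%, 0.0108% and 0.0706%. These shares count every member with a read. The miRNAs of embryonic stem cells had 1, 1 and 13 reads, and none reached the filter. From E90 to P30d, miR-499-5p and miR-133a-3p of the muscle list were at 1.04 and 1.48, and miR-128-3p and miR-218-5p of the neural list were at 0.75 and -0.29.

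In all, 109 of the 320 miRNAs were higher at P30d by 2-fold or more with an interval that excluded 0, 110 were lower and 101 were neither, and with TMM scaling the split was 113 to 106. Beyond those already named, the largest ratios among miRNAs with a mean of 100 CPM or more belonged on the higher side to miR-4792-3p (6.24), miR-130a-3p (5.07), miR-574-3p (4.59), miR-2887-5p (3.87) and miR-374a-3p (3.75). On the lower side they belonged to miR-184-3p (-9.25, interval -9.98 to -8.61), miR-542-3p (-6.55), miR-532-5p (-5.31), miR-503-5p (-5.26), miR-500-5p (-3.93) and miR-185-5p (-3.80). miR-184-3p, from chromosome 7 between 53883626 and 53883708, went from 3196 CPM to 5.24.

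The comparison of P30d with P7y covers growth to maturity and age. Here the log2 ratios of the 320 miRNAs had a median of -1.41 under CPM, which TMM scaling moved by 0.99 and DESeq2 scaling by 1.17, so single miRNAs are given relative to that median. Among the miRNAs higher at P7y were miR-101-3p, at 5.86 above the median, and the pair miR-143-3p (3.94) and miR-145-5p (3.58) from chromosome 2, miRNAs of smooth muscle that share a transcript. miR-10a-5p, encoded in a HOX gene cluster, stood at 3.51 and miR-375-3p, known from islet and epithelial cells, at 4.17, and miR-148b-3p at 4.09. miR-122-5p, the hepatocyte miRNA, was lower at P7y by more than the typical miRNA, at -1.09 relative to the median, and its share of reads was 3.79% against 21.4%. Far lower were miR-130a-3p at -5.26, miR-122-3p at -4.43 and miR-222-3p, a miRNA of endothelial and proliferating cells, at -3.28.

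Biliary and epithelial miRNAs had a median log2 ratio of 0.63 at percentile 99.3 of the random lists, yet their members went both ways, with 2 of 7 higher and 3 lower under CPM and 4 higher and 3 lower under TMM. The 2 higher under CPM were miR-375-3p and miR-31-5p, the latter named after its value was seen and read only 5 times at P30d. Mesenchymal miRNAs had a median of 0.12 at percentile 97.1, with 5 of 18 higher and 7 lower under CPM and 10 and 3 under TMM; miR-145-5p and miR-143-3p were higher, and miR-199a-5p was at -2.58 relative to the median of all miRNAs. Under CPM the let-7 family had 2 of 14 higher, let-7g-5p at 2.86 and let-7f-5p at 2.46 relative to the median, and 9 lower, against 2 and 5 under TMM; let-7a-5p, at -0.76 under CPM and 0.23 under TMM, passed the 2-fold rule under neither. Hepatocyte miRNAs had 4 of 23 higher and 13 lower under CPM, against 8 and 10 under TMM, with miR-148a-3p at 2.60 and miR-192-3p at -2.52 relative to the median.

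The median of the erythroid list turned from -0.13 under CPM to 0.86 under TMM, with 3 of 9 lower in both scalings, among them miR-16-5p and miR-144-3p at -1.89 and -1.87 relative to the median. Leukocyte miRNAs had 0 of 14 higher and 8 lower under CPM, and 2 and 6 under TMM, with miR-424-5p at -2.64 and miR-146a-5p at -1.36 relative to the median. DLK1-DIO3 miRNAs had 15 of 20 lower and 0 higher under CPM, but 9 lower and 2 higher under TMM, at percentile 40.8, and miR-483-3p was at -0.59 relative to the median, with 6.75 CPM at P7y. The miR-17-92 group had 2 of 14 higher and 8 lower under CPM and 4 and 5 under TMM, with miR-20a-5p at 2.87 relative to the median. The miR-30 family had 0 of 9 higher and 6 lower under CPM, and 3 and 3 under TMM. The miR-99, miR-100 and miR-125 families had 2 of 7 higher and 1 lower under CPM and 5 and 0 under TMM, with miR-100-5p at 2.72 relative to the median. Endothelial miRNAs had 0 of 10 higher and 5 lower under CPM, against 2 and 4 under TMM. The median of the ageing list turned from -0.85 under CPM, with 2 of 11 higher and 5 lower, to 0.14 under TMM, with 5 and 4. miR-499-5p of muscle and miR-128-3p of neural tissue were at -1.22 and -2.20 relative to the median.

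Under CPM 40 miRNAs were higher at P7y and 180 lower, with 100 neither, so that 18.2% of the differing miRNAs were higher; under TMM 85 were higher and 117 lower, and the share was 42.1%. The 10 largest ratios on the higher side included miR-2478-3p (5.62 relative to the median), miR-1260b-5p (5.68), miR-3968-5p (5.32) and miR-1260-5p (3.89), short miRNAs whose representative reads end in CCA, the bases that also end mature transfer RNAs. On the lower side they included miR-4792-3p (-7.42), miR-2887-5p (-4.31), miR-1307-5p (-4.23), miR-335-5p (-2.88), miR-425-5p (-2.77) and miR-5105-5p (-2.76). The hairpins of miR-2887 and miR-5105 lie on chromosome 6 between 866649 and 870961, a region whose predicted hairpins also differed between libraries.

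**Figure D2:**
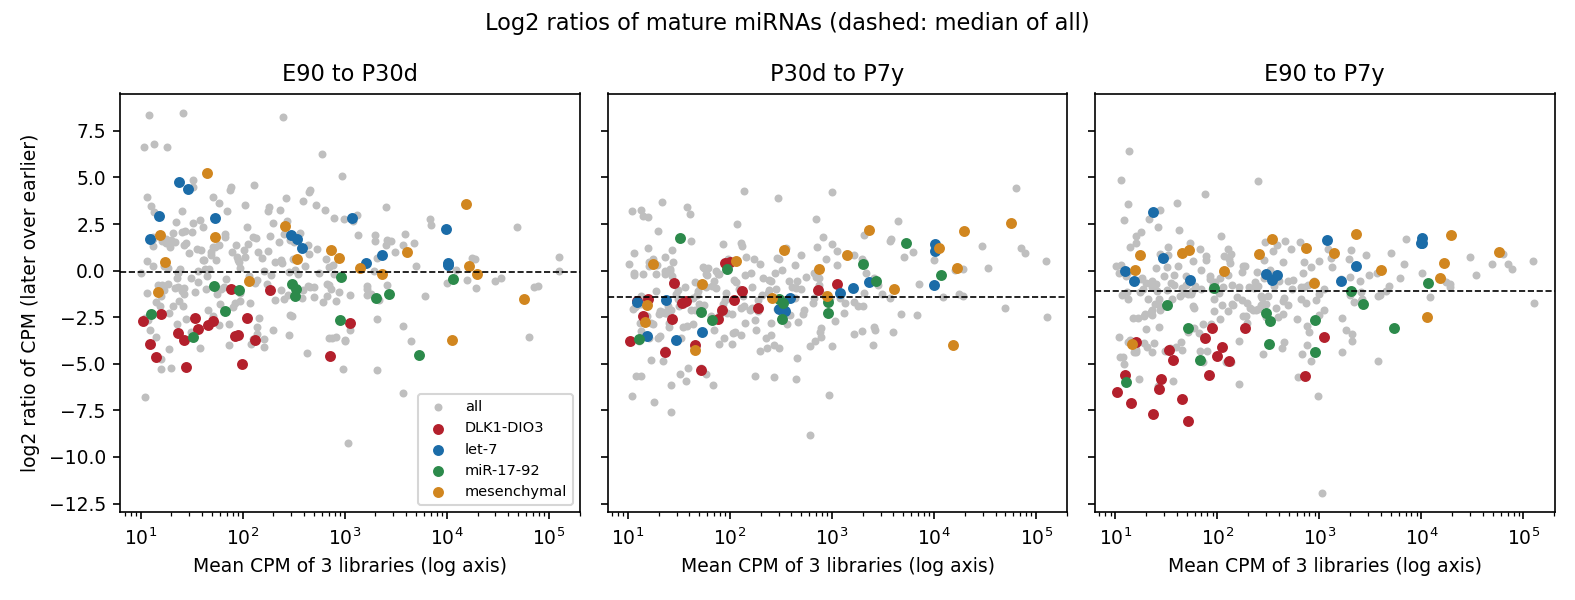
Log2 ratio of CPM, later over earlier library, against mean CPM (log axis) for the 320 mature miRNAs in each pair of stages, with 1 point per miRNA, members of 4 lists in colour and the median of all as a dashed line. The median lies at -0.09, -1.41 and -1.07 from left to right, and all 20 DLK1-DIO3 points from E90 to P7y lie below 0, under CPM and under TMM.

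The comparison of E90 with P7y sets fetal against mature liver. All 20 measured DLK1-DIO3 miRNAs, of 70 with a read, were lower at P7y under both CPM and TMM scaling, and so was miR-483-3p. The log2 ratios had a median of -1.07 under CPM, moved by 1.04 under TMM and 1.08 under DESeq2, and single miRNAs are again given relative to it. Among the miRNAs higher at P7y, the liver-enriched miR-802-5p stood at 5.88 above the median, miR-145-5p and miR-10a-5p of the mesenchymal list at 3.05 and 2.98, and let-7g-5p at 2.83. miR-184-3p, with 0.806 CPM at P7y, was at -10.88, the cell-cycle-linked miR-503-5p and miR-424-5p were at -5.65 and -4.63, and miR-483-3p was at -5.00.

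The DLK1-DIO3 median log2 ratio was -5.22, at percentile 0, with 3 members that had no read at P7y entered at the 3-read limit; miR-409-5p was at -4.59 and miR-127-3p at -2.48 relative to the median of all miRNAs. The list as a whole held 0.762% of miRNA reads at E90, 0.1005% at P30d and 0.0436% at P7y. The miR-17-92 group had 12 of 14 members lower and 0 higher under CPM (median -2.67, percentile 0.87) and 9 lower and 0 higher under TMM, with miR-20a-5p at -2.01 relative to the median of all, while miR-92a-3p, at -0.68 under CPM and 0.36 under TMM, passed the 2-fold rule under neither. All 9 erythroid miRNAs were lower under CPM (median -2.82, percentile 1.24, but 2.56 without the chromosome 6 region and 9.31 with only the more abundant arm of each member), and 6 under TMM, with miR-144-5p at -3.05 and miR-144-3p at -1.91 relative to the median of all, and miR-451-5p at 1223 CPM against 3941.

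Mesenchymal miRNAs had 6 of 18 higher and 2 lower under CPM and 14 higher and 2 lower under TMM (median 0.86, percentile 99.98), and held 18.02% of miRNA reads at P7y against 11.3% at E90; miR-143-3p was at 2.08 and miR-195-5p at 2.79 relative to the median of all, and miR-152-3p at -1.43. The ageing list had 4 of 11 higher and 1 lower under CPM and 8 and 0 under TMM (median 0.52, percentile 98.7), with miR-29a-3p at 2.18 and miR-146a-5p, which the leukocyte list also holds, at 2.65 relative to the median. The let-7 family had 5 of 14 higher and 0 lower under CPM and 8 and 0 under TMM (median 0.12, percentile 96.1), with let-7b-5p at 2.69 and let-7a-5p at 2.53. Its share of reads was 1.94% at E90, 4.10% at P30d and 4.95% at P7y.

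The median of the hepatocyte list turned from -0.28 under CPM, with 3 of 23 higher and 7 lower, to 0.76 under TMM, with 10 higher and 3 lower. miR-122-5p was lower at P7y, at -0.68 relative to the median, and past the 2-fold rule under CPM but not under TMM. The medians of the miR-30 family and of the leukocyte list also turned with scaling, from -0.67 to 0.37 and from -0.58 to 0.46; the miR-30 family had 0 of 9 higher and 4 lower under CPM against 2 and 0 under TMM, and the leukocyte list 2 of 14 and 5 against 5 and 2. Biliary miRNAs had 0 of 7 higher and 5 lower under CPM and 1 and 3 under TMM, with miR-375-3p, at -0.87 under CPM and 0.17 under TMM, past the 2-fold rule under neither. Endothelial miRNAs had 0 of 10 higher and 5 lower under CPM and 3 and 4 under TMM, with miR-221-3p at -2.10 relative to the median. The miR-99, miR-100 and miR-125 families had 1 of 7 higher and 0 lower under CPM and 4 and 0 under TMM, with miR-125b-5p at 2.76. Of the muscle and neural lists, miR-499-5p (under CPM) and miR-128-3p (under CPM and TMM) were lower at P7y, at -0.51 and -1.78 relative to the median, while the median of the muscle list turned from -0.35 under CPM to 0.69 under TMM.

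Under CPM 39 miRNAs were higher at P7y, 163 lower and 118 neither, and higher miRNAs made up 19.3% of those that differed; under TMM 86 were higher and 107 lower, a share of 44.6%. Further miRNAs with a mean of 100 CPM or more and large ratios were miR-6243-3p (2.91 relative to the median) and miR-23a-3p (2.62) on the higher side, and miR-421-3p (-3.85), miR-500-5p (-3.82), miR-362-5p (-3.79), miR-758-3p (-3.77) and miR-542-3p (-3.77) on the lower side.

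**Figure D3:**
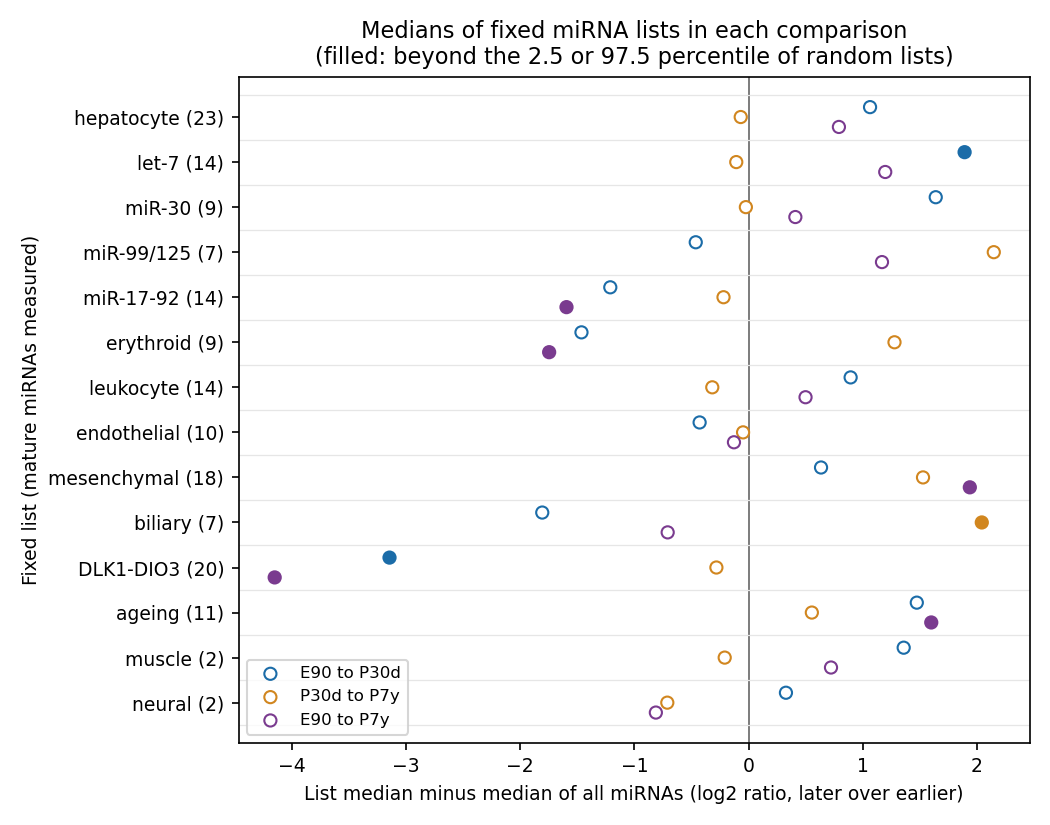
Median log2 ratio of each fixed list minus the median of all 320 miRNAs, for the 3 pairs of libraries, with the number of measured members in brackets and filled points outside the central 95% of 10000 random lists. Relative to all miRNAs, the DLK1-DIO3 list stood at -3.14 from E90 to P30d and -4.15 from E90 to P7y; a scaling moves every miRNA of a pair alike and leaves these differences as they are.

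Across the 3 stages, 92 miRNAs were highest at E90, 92 at P30d and 15 at P7y, each by 2-fold or more over both other libraries, and 25, 25 and 106 were lowest. With TMM the highest counts were 69, 72 and 41 and the lowest 50, 45 and 52. Under CPM, the largest levels among those highest at E90 belonged to miR-152-3p and miR-20a-5p, at P30d to miR-26a-5p and miR-199a-5p, and at P7y to miR-143-3p and miR-10a-5p. Also under CPM, miR-101-3p and miR-143-3p were among those lowest at P30d and miR-122-5p among those lowest at P7y.

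The arms of a hairpin were compared within each library, which no scaling between libraries affects. For 175 hairpins with at least 50 reads in every library, the balance of 5p to 3p reads differed by 2-fold or more with an interval off 0 in 111 from E90 to P30d, 120 from P30d to P7y and 85 from E90 to P7y. In 15, 11 and 8 of them the more abundant arm was a different one, against 9, 7 and 6 among the 137 hairpins with at least 200 reads. miR-144, an erythroid miRNA on chromosome 12, gave 10799 5p and 9038 3p reads at E90, 198 and 4328 at P30d and 664 and 1225 at P7y, a shift of -4.70 (interval -4.92 to -4.50) from E90 to P30d. miR-335 gave 762 and 1684 reads, then 1754 and 466, then 246 and 1069, and shifted by 3.05 and by -4.03. miR-199a gave 30954 and 27840, then 145688 and 22148, then 25183 and 30321 reads. miR-574 moved toward 3p throughout, from 511 and 130 reads to 196 and 1225 and to 9 and 307. miR-101 gave 8 and 604455 reads, then 97 and 19901, then 9 and 1190086, and shifted by 8.44 and by -9.26. Its arms thus went opposite ways in both pairs with P30d. The median size of the shift was 1.95, 2.11 and 1.25.

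**Figure D4:**
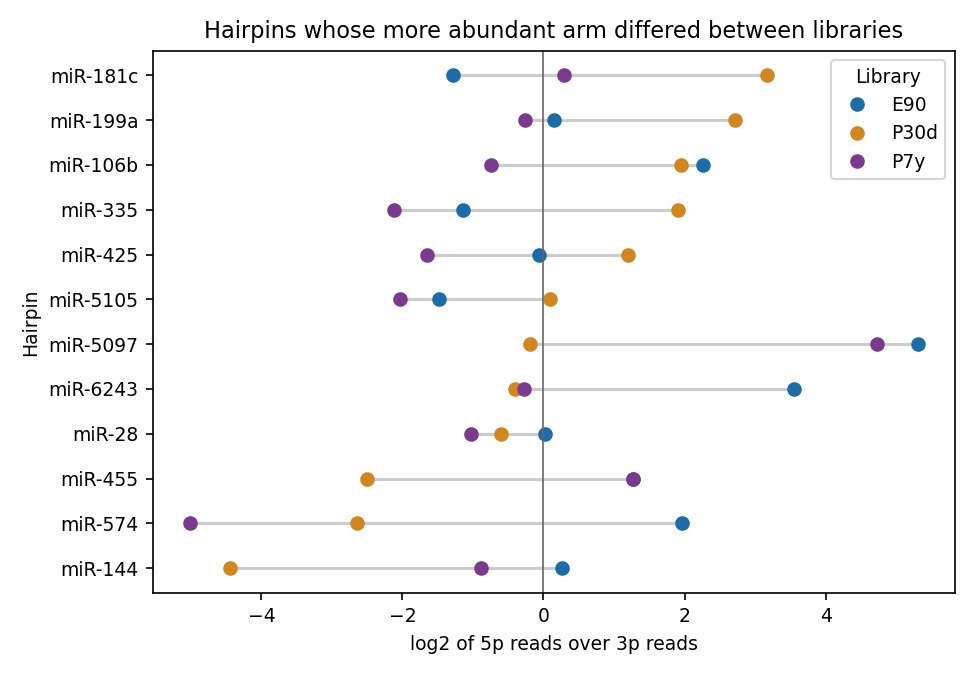
Log2 of 5p over 3p reads in each library for 12 hairpins with at least 200 reads per library whose more abundant arm differed between libraries by 2-fold or more, with 1 point per library. Each among its own 3 points, miR-144 lies furthest toward 3p and miR-335 furthest toward 5p at P30d, while miR-574 lies on the 5p side at E90 and on the 3p side at P30d and P7y.

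Read ends were described through the representative read that each table lists for a hairpin arm. Arms whose representative read was shorter than the reference at its 3′ end held 18.9% of miRNA reads at E90, 21.0% at P30d and 23.6% at P7y, and arms with a 3′ extension held 16.9%, 7.06% and 18.6%. Arms with a shifted 5′ end held 1.27%, 2.10% and 1.199%. For miR-122-5p the representative read was TGGAGTGTGACAATGGTGTTTGA at E90, which carries T23A against the reference (counted from 1 at the 5′ end), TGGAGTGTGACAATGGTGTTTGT at P30d and TGGAGTGTGACAATGGTGTTT at P7y, with 366069, 288421 and 123896 copies. By length of the representative read, 36.0% of miRNA reads belonged to 21 nt at E90, 25.5% at P30d and 49.5% at P7y. At 22 nt the shares were 34.6%, 34.6% and 39.6%, and at 23 nt 20.1%, 27.5% and 4.13%. All reads of an arm take the length of its representative read, so 1 abundant miRNA can move these shares. miR-122-5p, with 12.8% of miRNA reads at E90 and 21.4% at P30d, made up most of the 23 nt share there. At P7y it was counted at 21 nt. Representative reads of 18 to 20 nt were more frequent at P30d, with 0.436%, 4.17% and 0.409% at 20 nt and 0.231%, 1.49% and 0.193% at 18 nt. Those of 17 nt were least frequent there, with 0.210%, 0.0301% and 0.263%, as were those of 16 nt, with 0.0804%, 0.0637% and 0.211%. Arms shortened at the 3′ end by 2 nt or more held 0.769%, 4.68% and 4.39%, and miR-122-5p made up most of this share at P7y. Reads with a mismatch to the reference made up 18.6%, 13.9% and 21.7%.

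Predicted hairpins without a known miRNA held 1.73% of the table at E90, 4.03% at P30d and 0.150% at P7y, with 1149, 322 and 363 candidate sequences. Of these, 40, 29 and 21 had 50 reads or more.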

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

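The tests of the mismatched share and the T23A share of miR-122-5p, the repeats with at least 10 reads per arm or over hairpins highest or lowest at P30d, the thinned run, the run without the chromosome 6 region and the rule for predicted hairpins were chosen only after the results were seen.

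A predicted hairpin 983 bases from miR-483 on an unplaced scaffold, which starts at 1631 there, stood out because the report's comparisons do not use it and its reads lay far above what a count of 0 allows. It held 15339 CPM at E90, 541 at P30d and 40.1 at P7y, and its 3p read TGGTGCCTGACGTCTTGGCAGT made up most of this, with 126173 reads at E90. miR-483 itself, on the same scaffold and strand, held 445 CPM, 25.9 and 6.25 at that place.

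Another predicted hairpin, on chromosome 6 from 870046 to 870306, stood out for the same reason. It held 33731 CPM at P30d, 3.24% of that table, and had 0 reads at that place in the tables of E90 and P7y. Predicted hairpins of this region start at other places in those tables, such as 868164 at E90 and 872272 at P7y. The 0 therefore holds for this place in the tables and does not show that the sequence was absent from those libraries. The whole stretch from 860000 to 880000 held 0.433% of the table at E90, 4.48% at P30d and 0.212% at P7y, and part of its reads carry names of known miRNAs such as miR-2887 and miR-5105.

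At P30d, the stage between the others in age, 117 of 320 miRNAs were highest or lowest by 2-fold or more, against 117 at E90 and 121 at P7y, so the count does not set P30d apart. Which libraries lay closest depended on the measure: r of log2 CPM was 0.729 for E90 with P30d, 0.846 for P30d with P7y and 0.826 for E90 with P7y, while 68.4%, 69.4% and 63.4% of miRNAs differed by 2-fold or more under CPM. These shares depend on the scaling, whereas the SD of the log2 ratios does not, at 2.64, 2.16 and 2.35 in the same order. Expression that moves whole hairpins was tested by whether their arms moved together, over 175 hairpins, which are not replicates. From P30d to P7y r was -0.0766 (interval -0.222 to 0.0725), under the bound of 0.2 set in advance. Over the 84 with an arm highest or lowest at P30d it was -0.0403 (-0.253 to 0.176). In all 175 it was 0.402 from E90 to P30d and 0.434 from E90 to P7y. With at least 10 reads per arm r was 0.0986 (-0.0988 to 0.288) from P30d to P7y, 0.358 from E90 to P30d and 0.621 from E90 to P7y. By r itself the bound of 0.2 was thus met in each of these runs from P30d to P7y. In no pair with P30d did r reach the higher bound set in advance for arms that move together. Once arms with few reads were left out, the interval from P30d to P7y reached past 0.2, so such expression stays open. For lower depth at P30d, the E90 and P7y reads were thinned to the P30d total, which left 118. By the bound written for this run, a count that does not fall by 1.5 times goes against lower depth. After thinning, 92, 93 and 16 miRNAs were highest at E90, P30d and P7y, and 22, 25 and 109 were lowest, so no count moved by 1.5 times. These values argue against unequal depth as the source of the P30d count. Thinning leaves the P30d reads as they are, so other effects of fewer reads there stay open. A difference in read ends or ligation at P30d may have contributed and stays open. Arms parted 1.30 times as widely in pairs with P30d as from E90 to P7y, between the bounds set in advance. With at least 10 reads per arm, a repeat chosen after the results were seen, they parted 1.74 times as widely. That value passes the bound of 1.5 set in advance for a difference in read ends or ligation. Arm choice that differs with age, and age itself, are untested, since each stage has 1 library.

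The representative read of miR-122-5p at E90 ends in A through T23A, with 366069 copies, which are 30.9% of the reads of this miRNA there. Mismatched reads made up 34.5% of miR-122-5p at E90, 10.04% at P30d and 25.1% at P7y. The general rate of mismatches in the E90 library stays open: the share at E90 lay at percentile 90.7 among 75 other miRNAs with at least 10000 reads (median 9.59%), but the T23A read alone made up 89.8% of the mismatched reads, and a rank by all mismatches cannot account for 1 base. Addition of A to miRNA ends in general stays open. Only 6 representative reads with a substituted last base, from 4 miRNAs, were found among miRNAs with at least 1000 reads. The 16.7% of them that ended in A (interval 0.421 to 64.1) was the miR-122-5p read in question, so this share is not an independent test. A difference between stages in how this miRNA is trimmed or extended was not tested.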

How the results depend on the processing

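The run without the chromosome 6 region and the thinned run were chosen after seeing the data. Of 103 alternative values of the main results 60 stayed within 1.5 times the count, or within the interval of the share, and 43 did not; of 1782 values of named miRNAs 829 left the counting interval of the ratio and 4 more changed sign where the ratio had a call. Of 264 values each, 222 left the interval with DESeq2, 211 with TMM and 165 with the total without the 5 most abundant miRNAs; with reads without a mismatch it was 161 of 258, with known pig miRNAs only 49 of 213, without the chromosome 6 region 11 of 255 and with reads split among names 10 of 264. The counts of hairpins whose arm balance shifted by 2-fold stayed within 1.5 times with at least 200 reads per hairpin. Those whose more abundant arm changed went from 15, 11 and 8 to 9, 7 and 6. Of the list medians, 8 lay outside the central 95% of random lists, and TMM and DESeq2 leave these percentiles as they are by construction. Without the chromosome 6 region there were 7, as the erythroid list from E90 to P7y moved from percentile 1.24 to 2.56. With only the more abundant arm there were 8, but not the same lists, and 22 of 48 medians moved by 0.1 or more: erythroid from E90 to P7y (9.31) and let-7 from E90 to P30d (93.3) were no longer among them, and hepatocyte from E90 to P7y (97.9) and mesenchymal from P30d to P7y (97.9) were. No paired analysis was possible because each stage has 1 library. Depth limits low counts most at P30d, where 0 reads allow 0.828 CPM.

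Without a filter more miRNAs were compared, and with 100 CPM fewer, which by construction moves counts. Without a filter 191 were higher and 197 lower from E90 to P30d, 64 and 334 from P30d to P7y, and 89 and 340.0 from E90 to P7y. With 100 CPM, 58 were higher and 55 lower from E90 to P30d, 91 were lower from P30d to P7y, and 21 were higher and 81 lower from E90 to P7y; 43 were highest at E90, 52 at P30d and 8 at P7y, and 12 were lowest at E90 and 50 at P7y. With known pig miRNAs only, 26 were higher from P30d to P7y and 24 from E90 to P7y, again from fewer miRNAs. TMM and DESeq2 shift all log2 ratios of a pair alike. From P30d to P7y, 85 were higher and 117 lower with TMM, and 96 and 101 with DESeq2. From E90 to P7y, 86 were higher and 107 lower with TMM, and 87 and 106 with DESeq2. Highest at P7y were 41 with TMM and 41 with DESeq2. Lowest were 50 at E90, 45 at P30d and 52 at P7y with TMM, and 48, 58 and 46 with DESeq2.

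The 10 most abundant miRNAs held 61.5% at E90 and 76.3% at P7y when only representative reads were counted, and 63.2% at E90 with reads split among names; the cause was not tested. Without the most abundant miRNA of each library, which leaves fewer reads in the total, shortened 3′ ends held 21.6% at E90, 26.8% at P30d and 27.9% at P7y, and extended ones 19.4%, 8.98% and 22.0%. From E90 to P30d, miR-6243-3p turned to -0.0373 without the chromosome 6 region, which removes part of its hairpins. From P30d to P7y, miR-409-5p turned to 0.11 and miR-758-3p to 0.0614 with DESeq2, which shifts every ratio, and miR-758-3p to 0.21 with reads without a mismatch, where the cause was not tested.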

Other observations

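The groupings in this part, by genomic cluster and by read end, were chosen only after the results were seen, and they are given as values without explanation.

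Hairpins within 10 kb of each other on a strand formed 9 clusters of at least 3 measured hairpins. The cluster of miR-188, miR-362, miR-500, miR-532 and miR-660 on chromosome X from 48632024 to 48640903 was lower at P30d than at E90 in 7 of 8 mature miRNAs (median log2 ratio -3.52) and lower at P7y in all 8 (-4.43, and -3.39 with TMM). Lower at P7y than at E90 in all 5 measured miRNAs was the cluster of miR-450a, miR-450b, miR-450c and miR-542 on an unplaced scaffold, with a median of -4.48, and -3.44 with TMM. The cluster of miR-182, miR-183 and miR-96, which sensory organs and erythroid cells express, on chromosome 18 from 20030634 to 20035303, had a median of -3.17 from E90 to P30d and -2.89 from E90 to P7y, -1.85 with TMM. It overlaps the erythroid list: its highest log2 ratio from E90 to P7y, -2.82, is the median of that list. In the opposite sense, miR-23a, miR-24 and miR-27a on chromosome 2 from 65581838 to 65582254 had a median of 2.67 from E90 to P30d with 3 of 3 higher, and 1.18 from E90 to P7y, 2.22 with TMM. From P30d to P7y that cluster was lower in 3 of 3 under CPM, at -1.49, and at -0.50 with TMM.

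The representative reads of 11 measured miRNAs, miR-2478-3p and miR-1260b-5p among them, ended in CCA in every library, as mature transfer RNAs do. These miRNAs held 0.328% of miRNA reads at E90, 0.105% at P30d and 0.484% at P7y. From E90 to P30d 2 of them were higher and 6 lower, and from P30d to P7y 8 were higher and 2 lower under CPM and 9 and 2 under TMM.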
